A study of Mus musculus with 6 samples.

How the data were processed

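Gene expression was measured by RNA sequencing in 6 libraries of mouse bone marrow-derived macrophages, 3 labelled wild type (WT) and 3 labelled Mettl3 knockout (KO). Per the labels' protocols, total RNA was extracted with Trizol, and poly(A) RNA was fragmented and reverse-transcribed. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.0.4 and StringTie 1.3.4d were used with the mouse build mm10. Their settings, the annotation release, the strand of the library kit and any filter are not given in the sources used here. The deposited table lists 55401 genes with 2 values per library and annotation terms from GO and KEGG. Per the file headers, the first value is FPKM (mapped fragments scaled for transcript length and library size), which the authors computed per gene and library. Genes with a count of 0 carry an FPKM of 0.0001 there. The second value is an estimated count per gene, deposited as whole numbers, and its totals differ between libraries. Among genes with counts of 1 to 20, multiples of 4 made up 36.9% to 40.4%, where an even spread gives 25%, so a low estimated count is not a tally of single reads. Every column of values per library was used.

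Library totals ran from 67280390 to 77997742 estimated counts. At a mean count of at least 10000, the median coefficient of variation of FPKM between replicates was 1.93% in WT and 2.02% in labelled KO (1378 genes). Of the gene identifiers, 99.5% were in GENCODE M21, an annotation of the same build, and 94.2% of those had the same coordinates. Coordinates are those of the deposited table. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart.

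Samples were grouped by the genotype in their labels, and the comparison was labelled KO against WT. Groups, tests, gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The plan was limma on log2(FPKM + 0.1), with edgeR's quasi-likelihood test as the main test if counts were present. Because the table holds estimated counts, they were rounded and tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr with its minimum count of 10 and minimum total of 15, glmQLFit and glmQLFTest). Adjusted p-values are from the Benjamini-Hochberg procedure over the 16256 tested genes, and a gene was called at an adjusted p under 0.05 with no minimum fold. Standard errors were taken from the fold change and its F statistic, and 95% limits from the t distribution with 4 residual degrees of freedom. FPKM values are given as mean ± SD of 3 libraries.

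Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with the preset correlation of 0.01, adjusted over the 37 of 39 lists with at least 5 tested members. Camera asks whether the mean test statistic of a list's genes differs from that of the other genes. Listed genes were found by symbol or by an older symbol, and those found by neither were left out. The lists cover the m6A machinery; interferon gamma-responsive GTPases and type I interferon-stimulated genes; sensing of double-stranded RNA and DNA; NF-kB targets, Toll-like receptor signalling and inflammasome genes; MHC class I and II; complement; chemokines and chemokine receptors; macrophage identity, phagocytic receptors and alternative activation; lysosome, matrix remodelling, cholesterol biosynthesis and cholesterol efflux. Further lists cover NRF2 targets, the unfolded protein response, p53 targets, hypoxia, glycolysis, oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, histones, the cell cycle and immediate early genes. Markers of monocytes and progenitors, neutrophils, dendritic cells, T and NK cells, B and plasma cells, mast cells and their relatives, erythroid cells and megakaryocytes, stromal cells, and endothelial cells and adipocytes were also listed. Some genes stand in several lists. Terms of the deposited table with 10 to 300 tested members were tested in the same way.

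The genes named are Mettl3, Lyz2, Csf1r, Adgre1 and Itgam; the 12 largest rises and 12 largest falls among called genes with a symbol, no overlap between groups and a mean FPKM of at least 2 in the higher group; the 6 other called genes with the smallest adjusted p; every m6A gene; and up to 4 called members of each list by adjusted p, or where none was called the 2 with the highest FPKM. Tox4, Lyz1, Tor1aip2, B2m, Cd55, Cd93, Gsr, Trac, Cd3e and Psap were named after their values were seen. A gene that this rule would name is not reported here.

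Alternatives were DESeq2 1.42.0, edgeR without a filter, with an FPKM filter or with median-of-ratios factors, a replicate block, each library left out, a 2-fold minimum, and limma on log2(FPKM + pseudocount) with pseudocounts of 1 and 0.01 and with other filters, scalings and weights. For lists these included the estimated correlation and fry, which asks whether a list's own genes move one way on balance. With an estimated correlation, camera uses the 4 residual degrees of freedom, far fewer than with the preset. Its p-values then rise even where the correlation does not. Chosen after seeing the data were counts divided by 4, limma with its planned pseudocount of 0.1, edgeR with the FPKM filter of 1, fry on the terms, removal of the length and GC trend of each library, and a minimum mean log2 CPM of 3. Transcript lengths, GC content and GGACT sites came from GENCODE M21. The regression of log2 fold change on GGACT sites held splines of log length, GC content and log2 CPM, over genes with a mean log2 CPM of at least 3, and was run with and without log exon number, which its prediction did not name.

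The fits were tested on simulated data, 10 tables of 16256 genes with 200 changed genes each (mean count at least 50). For labelled KO against WT, edgeR recovered 66.7% of genes changed 2-fold, 32.8% at 1.5-fold and 1.04% at 1.25-fold, and 5.24% of its calls were unchanged genes. DESeq2 recovered 81.4%, 62.2% and 15.2%, and 33.3% of its calls were unchanged genes. limma recovered 57.3%, 19.0% and 0.448%, with 6.62%. A first version with 1 table required more than 80% recovery at 2-fold and failed, so it was replaced by the 10 tables, which require a median log2 fold change within 0.1 of the simulated 2-fold change, under 10% unchanged genes among edgeR's calls and recovery of a raised list. The simulation took its spread from estimates per gene that also hold the spread of the low counts, and called genes of the real table had a median absolute log2 fold change of 0.30, so the simulated recovery does not measure what these libraries can detect. Camera called a list of 30 genes raised 1.2-fold in 10 of 10 tables and an unchanged list in 1 of 10. Genes were simulated independently, so this does not show how often camera calls unchanged lists whose members are correlated.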

Results

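RNA from mouse bone marrow-derived macrophages was sequenced in 6 libraries. These cells are grown from bone marrow in the cytokine M-CSF, here at 40 ng/mL with 10% serum for 7 days, and the bone marrow came from C57BL/6 mice. The labels describe 3 libraries as wild type (WT) and 3 as Mettl3 knockout (KO), and the series compares the transcripts of the 2 genotypes. Mettl3 encodes the catalytic subunit of the enzyme that writes N6-methyladenosine (m6A) on messenger RNA. The growth conditions are said to precede a treatment that the labels do not name. The WT libraries held 67280390, 68001446 and 68658821 estimated counts and the libraries labelled KO held 75201178, 68145877 and 77997742, with 19476 to 19825 genes above a count of 0. Lyz2, which encodes lysozyme M, took the largest share of counts in each WT library, 2.07% to 2.14%. In the libraries labelled KO the largest share, 1.89% to 1.91%, belonged to Psap, which encodes the lysosomal protein prosaposin. Mitochondrially encoded genes took 2.53% to 3.11% of counts over all 6 libraries. Correlations of log2 CPM were 0.975 to 0.979 within groups and 0.971 to 0.975 between them, and the first principal component, with 28.0% of the variance, separated WT from labelled KO. The labels do not say that the replicates came from separate mice or cultures, so p-values measure only the spread between these samples, which may be technical.

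Mettl3, the targeted gene, was not lower in the libraries labelled KO. The gene (ENSMUSG00000022160) lies on chromosome 14 from 52294841 to 52305128 on the minus strand of mm10. Its FPKM was 2.62, 2.91 and 2.26 in the WT libraries and 2.504, 2.56 and 2.93 in those labelled KO, on 887 to 1309 estimated counts. The means were 2.59 ± 0.323 and 2.67 ± 0.233 (SD, n = 3 each). The log2 fold change of labelled KO over WT was 0.02 (SE 0.11, edgeR adjusted p = 0.93), with 95% limits of -0.29 and 0.34, a ratio between 0.816 and 1.26. An exact two-sided permutation test over the libraries gave p = 0.9, where the smallest value that 3 against 3 allows is 0.1. The sign of the Mettl3 change turned to -0.07 without WT replicate 3 and to -0.06 without KO replicate 3. Mettl3 shares 933 of its 5076 annotated exonic bases, 18.4%, with Tox4 on the opposite strand, and the values here are totals per gene that do not tell exons apart. Tox4 was far above Mettl3, at 17.7 FPKM in WT and 18.8 in labelled KO. Its reads could make up an unknown share of the Mettl3 value, so the ratio may not describe Mettl3 alone. Because Mettl3 did not follow the genotype label, directions are stated for "the libraries labelled KO" throughout.

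Of the macrophage genes fixed in advance, Lyz2 and Adgre1 fell and Csf1r rose in the libraries labelled KO. Lyz2 (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321, minus strand) read 14098, 14431 and 14037 FPKM in WT and 5943, 6026 and 6066 FPKM in labelled KO. The ratio was 0.419 and the log2 fold change -1.26 (SE 0.013, edgeR adjusted p = 3.33e-07). The exact permutation p of Lyz2 was 0.1, the smallest possible. Csf1r, the M-CSF receptor, went from 569 ± 1.15 to 687 ± 5.61 FPKM (SD, n = 3), a log2 fold change of 0.26 (edgeR adjusted p = 3.14e-05). Adgre1, which encodes the F4/80 antigen, went from 492 ± 2.78 to 396 ± 12.1 FPKM, a log2 fold change of -0.33 (edgeR adjusted p = 0.000368). Itgam, which encodes CD11b, did not pass, at 142 ± 43.5 FPKM in WT and 183 ± 27.0 in labelled KO (log2 fold change 0.35, SE 0.24, edgeR adjusted p = 0.426), and WT replicate 2 read 92.3 FPKM. Lyz2 reads can be shared with its paralog Lyz1, which was at 39.9 FPKM in WT and 49.1 in labelled KO and was not called.

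**Figure D1:**
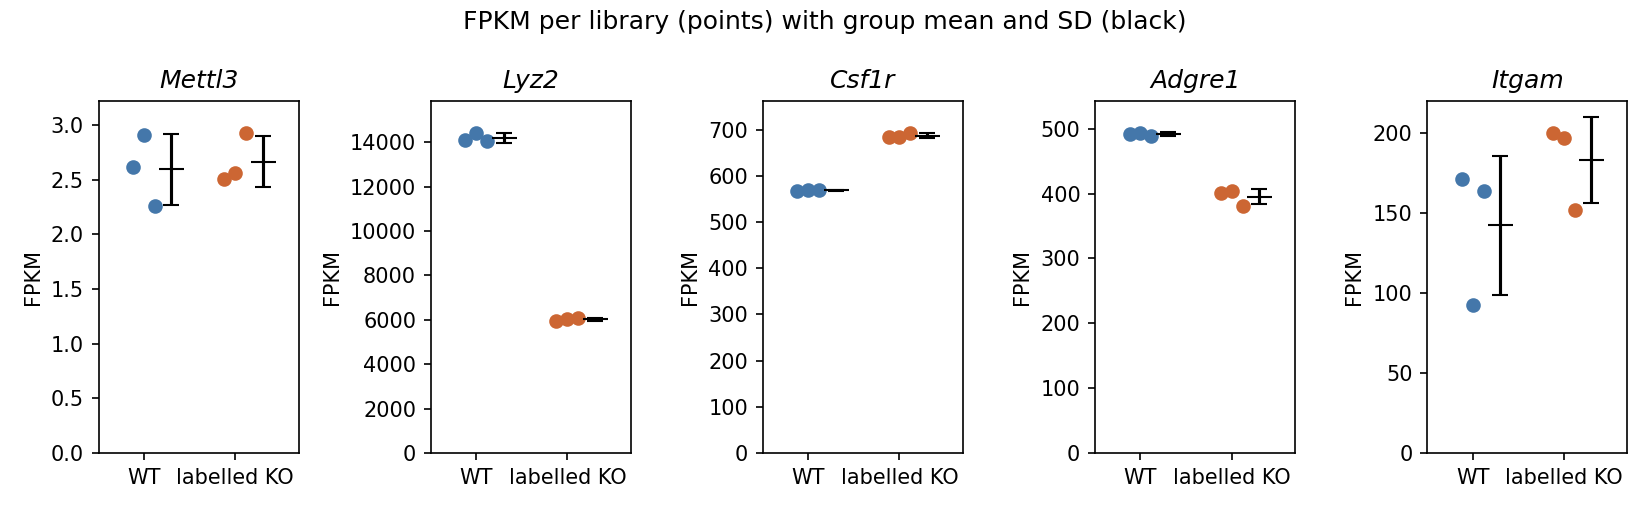
FPKM of Mettl3, Lyz2, Csf1r, Adgre1 and Itgam in each library (points; WT blue, labelled KO orange), with the group mean and SD of 3 libraries in black; each vertical axis starts at 0. Mettl3 overlaps between the groups, and Lyz2 lies between 5943 and 6066 in every library labelled KO against 14037 or more in every WT library.

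Over the transcriptome, 2060 of 16256 tested genes (12.7%) differed between the groups, 1139 higher and 921 lower in the libraries labelled KO (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Most changes were small: the median absolute log2 fold change of called genes was 0.30, and 114 genes passed a 2-fold change, 46 higher and 68 lower. At an unadjusted p under 0.05 there were 4301 genes. Leaving out 1 library lowered the count to 1305, 1244 and 1305 without WT replicates 1, 2 and 3, and to 1255, 1339 and 1277 without KO replicates 1, 2 and 3.

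The 12 largest rises in the libraries labelled KO included genes of the granzyme and guanylate-binding families. Apol7c, an apolipoprotein L gene, went from 5.43 ± 0.161 to 11.8 ± 0.403 FPKM (SD, n = 3), a log2 fold change of 1.10 (SE 0.059, edgeR adjusted p = 0.000173). Smpdl3b, which encodes a membrane-anchored phosphodiesterase, went from 23.2 ± 0.623 to 49.0 ± 1.15 FPKM, a log2 fold change of 1.07 (SE 0.038, edgeR adjusted p = 3.05e-05). Gbp4 rose by 1.04 (SE 0.046), from 13.7 to 28.4 FPKM, and its relative Gbp2b by 1.31 (SE 0.18), from 0.885 to 2.23 FPKM. The granzyme genes Gzmg and Gzmd rose by 1.14 (SE 0.087) and 1.09 (SE 0.079), each from about 10 FPKM (10.2 and 10.1). C1rb, Serpina3f, Mb21d2 and the gelatinase gene Mmp2 rose by 1.04, 1.06, 1.12 and 0.99. The zinc finger genes Zfp260 and Zfp865 rose by 1.52 (SE 0.26) and 1.14 (SE 0.26), from 0.932 and 1.5 FPKM. These last 2 calls were lost in some fits with 1 library left out, which hold fewer samples, though both genes stayed higher. That of Zfp260 was lost without WT replicate 3 (edgeR adjusted p = 0.0527), and that of Zfp865 without WT replicate 2 or 3 or KO replicate 2 or 3 (edgeR adjusted p from 0.113 to 0.122). Gbp4, Gbp2b, C1rb and the granzymes have close paralogs that can share reads, which makes their values uncertain.

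Among the largest falls in the libraries labelled KO, Tor1aip1 had the most reads behind it apart from Lyz2. Tor1aip1 (ENSMUSG00000026466, chromosome 1, 156004599 to 156036480, minus strand) encodes an inner nuclear membrane protein that binds torsin. It went from 61.8 ± 0.940 to 18.9 ± 0.307 FPKM (SD, n = 3), a log2 fold change of -1.72 (SE 0.025, edgeR adjusted p = 1.2e-06). Its end overlaps Tor1aip2 on the opposite strand, which was not called (log2 fold change 0.08). Cd5l, a secreted macrophage protein, went from 12.6 ± 0.191 to 4.57 ± 0.556 FPKM, a log2 fold change of -1.48 (SE 0.097). Cd83 fell by 1.18, the stress cytokine gene Gdf15 by 1.03, the linker histone gene H1f2 by 1.04 and the carbonyl reductase gene Cbr2 by 1.01 on the log2 scale. Zfp12 and Pcp4l1 fell by 1.45 and 1.08. Id3, a transcription inhibitor, fell by 1.01, a call lost without WT replicate 2 or 3 or KO replicate 1 (edgeR adjusted p from 0.0503 to 0.0547). Vma21, an assembly factor of the proton pump of the lysosome, fell by 1.79 (SE 0.37), a call lost without any 1 library other than WT replicate 3 (edgeR adjusted p from 0.0764 to 0.0915). Snora57, a small nucleolar RNA, fell by 2.22 (SE 0.53), a call lost without any 1 of the 6 libraries (edgeR adjusted p from 0.0742 to 0.157).

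Apart from Lyz2 and Tor1aip1, the 6 named genes with the smallest adjusted p-values all rose in the libraries labelled KO. Hp, which encodes haptoglobin, went from 165 ± 0.234 to 306 ± 3.15 FPKM (SD, n = 3), a log2 fold change of 0.88 (edgeR adjusted p = 5.47e-06). The complement genes C3 and Cfb rose from 377 to 520 and from 274 to 397 FPKM, by 0.45 and 0.52 (edgeR adjusted p = 5.47e-06 and 6.6e-06). Cd74, the invariant chain of MHC class II, and H2-Ab1, a class II beta chain, rose by 0.52 and 0.72 (edgeR adjusted p = 6.2e-06 and 6.6e-06). Ctsc, the protease that activates granzymes, rose by 0.52, from 169 to 245 FPKM.

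Genes induced by interferon gamma rose most uniformly in the libraries labelled KO. Of 21 tested GTPases and factors of that response, 17 were higher and 0 lower (19 and 0 adjusted over the list alone), with a median log2 fold change of 0.50 (camera adjusted p = 1.75e-19). Gbp5 rose from 23 to 40.3 FPKM (log2 fold change 0.79), Gbp2 from 187 to 260 (0.46) and Igtp from 92.6 to 134 (0.52), besides Gbp4. In the MHC class II list 9 of 16 genes were higher and 1 lower (10 and 1 adjusted over the list alone; camera adjusted p = 7.84e-07). H2-Eb1 and H2-Aa rose by 0.63 and 0.49, with Cd74 and H2-Ab1, and the gene that fell was Cd83. For MHC class I, 13 of 18 genes were higher and 1 lower (14 and 2 adjusted over the list alone; camera adjusted p = 3.29e-08). H2-Q7 rose by 0.65, H2-K1 by 0.25, and the chaperone genes Calr and Pdia3 by 0.43 and 0.36, while the gene that fell was B2m (-0.11). Gbp, H2 and other clustered families share reads between members, so single values are uncertain. In the same libraries the monocyte and progenitor markers were higher, with 8 of 15 called higher and 0 lower (9 and 1 adjusted over the list alone; median 0.41, camera adjusted p = 1.72e-07). Besides Hp, these included F13a1 (0.31), Vcan (0.43) and Plac8 (0.43).

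The complement and NF-kB lists were also called higher in the libraries labelled KO. In the complement list 9 of 16 genes rose and 2 fell (9 and 2 adjusted over the list alone; median 0.29, camera adjusted p = 8.05e-07). C1qa and C1qb, subunits of the first component, rose by 0.49 and 0.34, with C3 and Cfb, and the genes that fell were Cd55 (-0.21) and Cd93 (-0.15). Of 29 NF-kB cytokines and targets, 13 rose and 0 fell (16 and 0 adjusted over the list alone; median 0.19, camera adjusted p = 1.20e-06), and 6 to 8 were called with any 1 library left out. Nos2, the inducible nitric oxide synthase, rose from 10.5 ± 0.104 to 15.2 ± 0.456 FPKM (SD, n = 3), and Il1b from 13.4 ± 0.925 to 24.1 ± 0.956 FPKM. Icam1 and Birc3 rose by 0.21 and 0.30. The lists of monocyte markers and of T and NK cell markers moved in the same direction in these libraries. Of 17 T and NK cell markers, 3 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.34, camera adjusted p = 0.00792, but adjusted p = 0.0902 with an estimated correlation). Gzmb (14 to 20.2 FPKM) and Prf1 (1.56 to 3 FPKM) rose, Cd4 fell (18.0 to 11.6 FPKM), and Gzma rose by 0.72, a call lost without any 1 of the 6 libraries (edgeR adjusted p from 0.0554 to 0.137). The T cell receptor genes Trac and Cd3e, at 2.45 and 0.363 FPKM in WT and 3.21 and 0.438 FPKM in labelled KO, were not called.

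Genes of the m6A machinery other than Mettl3 tended upward in the libraries labelled KO. Of 24 writers, erasers and readers, 9 rose and 1 fell (11 and 2 adjusted over the list alone; median 0.19, camera adjusted p = 0.00651, but adjusted p = 0.109 with an estimated correlation), and 5 to 9 were called with any 1 library left out. The writer subunit gene Virma rose from 9.93 ± 0.216 to 12.3 ± 0.263 FPKM (SD, n = 3; log2 fold change 0.30), and the demethylase gene Alkbh5 from 20.9 ± 0.504 to 24.7 ± 0.142 FPKM (0.23). The reader gene Ythdf2 and the writer cofactor gene Rbm15b rose by 0.30 and 0.27, and the reader gene Igf2bp2 fell by 0.60 from a low level, 0.909 FPKM. Wtap rose by 0.69, Rbm15 by 0.41, Ythdc1 by 0.32, Prrc2a by 0.24 and Ythdf1 by 0.21. Each of these calls was lost in some fits with 1 library left out, which hold fewer samples, though no direction reversed. The call of Wtap was lost without WT replicate 3 or any 1 KO library (edgeR adjusted p from 0.0635 to 0.0772), and that of Rbm15 without any 1 library but WT replicate 3 (0.0711 to 0.103). Ythdc1 lost it without WT replicate 2 or 3 or KO replicate 1 or 3 (edgeR adjusted p from 0.107 to 0.124). Prrc2a lost it without WT replicate 3 or KO replicate 1 or 3 (edgeR adjusted p from 0.0517 to 0.0579), and Ythdf1 without WT replicate 2 or KO replicate 1 or 3 (0.0553 to 0.0591). The genes that did not pass were Mettl3, its partner Mettl14 (log2 fold change -0.13), Zc3h13 (0.20), Mettl16 (0.34), Fmr1 (-0.15), Cbll1 (0.96, SE 0.43), Hnrnpa2b1 (-0.06), Hnrnpc (-0.05), Fto (0.05), Ythdc2 (-0.07), Igf2bp3 (0.18), Zcchc4 (0.07), Mettl5 (0.06) and Ythdf3, whose FPKM was 20.8 in WT and 21 in labelled KO.

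Targets of the unfolded protein response and ATF4 were called higher as a list, with 10 of 27 genes higher and 2 lower in the libraries labelled KO (12 and 4 adjusted over the list alone). The median was 0.18 and the camera adjusted p = 0.0231, but adjusted p = 0.108 with an estimated correlation and 0.0671 over genes with a mean log2 CPM of at least 3. The endoplasmic reticulum chaperone genes Pdia4 and Hsp90b1 rose by 0.69 and 0.37. The genes that fell, Atf5 (-0.72) and the cystine transporter gene Slc7a11 (-0.72), are targets of ATF4.

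Ribosomal protein genes were lower in the libraries labelled KO by a small amount. Of 50 tested, 0 rose and 21 fell (0 and 33 adjusted over the list alone), with a median log2 fold change of -0.14 (camera adjusted p = 1.05e-13, but adjusted p = 0.0528 with an estimated correlation), and 13 to 18 were called with any 1 library left out. Rpl11 went from 91.5 ± 1.28 to 57.7 ± 2.5 FPKM (SD, n = 3; log2 fold change -0.68), and Rpl3, Rpl4 and Rpl8 fell by 0.26, 0.15 and 0.14. Every tested ribosomal protein transcript shares sequence with annotated pseudogenes, so these values are uncertain. Of 34 nuclear-encoded oxidative phosphorylation genes, 0 rose and 6 fell (0 and 12 adjusted over the list alone; median -0.12, camera adjusted p = 8.16e-06), and 3 to 6 were called with any 1 library left out. Sdhb and Sdhc, of complex II, fell by 0.21 and 0.24. Uqcrc1 fell by 0.21 and Atp5c1 by 0.20, calls lost without KO replicate 1 (edgeR adjusted p = 0.0501) and without WT replicate 1 or 2 (0.0511 and 0.0537). The 13 mitochondrially encoded genes were not called as a list (0 higher and 2 lower, also 0 and 2 adjusted over the list alone; camera adjusted p = 0.626). Their median and mean were above 0 (0.03 and 0.05) while the test leaned down. The genes called were mt-Nd1 (-0.15) and mt-Nd2 (-0.11), the latter not without WT replicate 1 or 2 or KO replicate 1 or 2 (edgeR adjusted p from 0.0950 to 0.108), and 1 to 5 were called with any 1 library left out.

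Type I interferon-stimulated genes moved against the interferon gamma group. Of 43 tested, 3 rose and 16 fell in the libraries labelled KO (4 and 23 adjusted over the list alone; median -0.09, camera adjusted p = 1.83e-06). Usp18, a brake on interferon receptor signalling, fell from 43.0 ± 0.682 to 29.6 ± 0.426 FPKM (SD, n = 3). The antiviral genes Bst2 and Rsad2 fell by 0.31 and 0.39, while Cxcl10, which interferon gamma also induces, rose by 0.67. The difference between these lists was not tested. Among 24 genes that sense double-stranded RNA or DNA, 2 rose and 4 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.311). Trex1 and Zbp1 rose by 0.33 and 0.11, and Oas1a and Ddx58 fell by 0.15 and 0.20. The median of that list was -0.02 and its mean 0.05, with the test leaning down.

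The NRF2 antioxidant, cholesterol efflux and chemokine lists were called lower in the libraries labelled KO. In the NRF2 antioxidant list 1 of 23 genes rose and 10 fell (2 and 12 adjusted over the list alone; median -0.19, camera adjusted p = 1.94e-06). Prdx1, Hmox1 and Ftl1 went from 373 to 289, from 492 to 403 and from 4222 to 3740 FPKM, with Slc7a11, and the gene that rose was Gsr (0.22). For cholesterol efflux and LXR targets, 0 of 28 rose and 12 fell (1 and 13 adjusted over the list alone; median -0.06, camera adjusted p = 0.000395, but adjusted p = 0.134 with an estimated correlation). The scavenger receptor gene Cd36 went from 46.6 ± 1.09 to 23.9 ± 0.380 FPKM (SD, n = 3; log2 fold change -0.98), and Lipa, Fabp4 and Plin2 fell by 0.20, 0.39 and 0.28. Of 21 chemokines, 1 rose and 8 fell (2 and 8 adjusted over the list alone; median -0.21, camera adjusted p = 0.00379, but adjusted p = 0.0826 with an estimated correlation and 0.0538 once length and GC trends were removed). Ccl9, Ccl8 and Ccl2 fell by 0.28, 0.38 and 0.42, and the chemokine that rose was Cxcl10.

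Lists of replication-dependent histones, p53 targets and cell cycle genes were called lower in the libraries labelled KO with the preset correlation, and none of them with an estimated one. Of 11 replication-dependent histone genes, 0 rose and 3 fell (0 and 3 adjusted over the list alone; median -0.57, camera adjusted p = 0.0112, but adjusted p = 0.105 with an estimated correlation). H1f2 and H2bc4 fell by 1.04 and 0.64, and H3c4 by 1.09, a call lost without any 1 of the 6 libraries (edgeR adjusted p from 0.0564 to 0.0939). Most such transcripts lack the poly(A) tail by which this RNA was selected, and the histone genes share reads with each other. Of 27 p53 targets, 3 rose and 7 fell (3 and 8 adjusted over the list alone; median -0.07, camera adjusted p = 0.00858, but adjusted p = 0.0902 with an estimated correlation), and 6 to 8 were called with any 1 library left out. Cdkn1a and Plk2 fell by 0.29 and 0.54, with Gdf15, and the death receptor gene Fas rose by 0.45. Of 40 cell cycle genes, 0 rose and 1 fell (0 and 0 adjusted over the list alone; median -0.20, camera adjusted p = 0.00207, but adjusted p = 0.0902 with an estimated correlation). The cell cycle call was also lost with genes at a mean log2 CPM of at least 3 (camera adjusted p = 0.0546) and at an FPKM of at least 5 (0.868). Its called gene, Ube2c (-0.53), lost the call without any 1 library but WT replicate 3 (edgeR adjusted p from 0.0747 to 0.109), and 0 to 2 members were called with any 1 library left out.

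**Figure D2:**
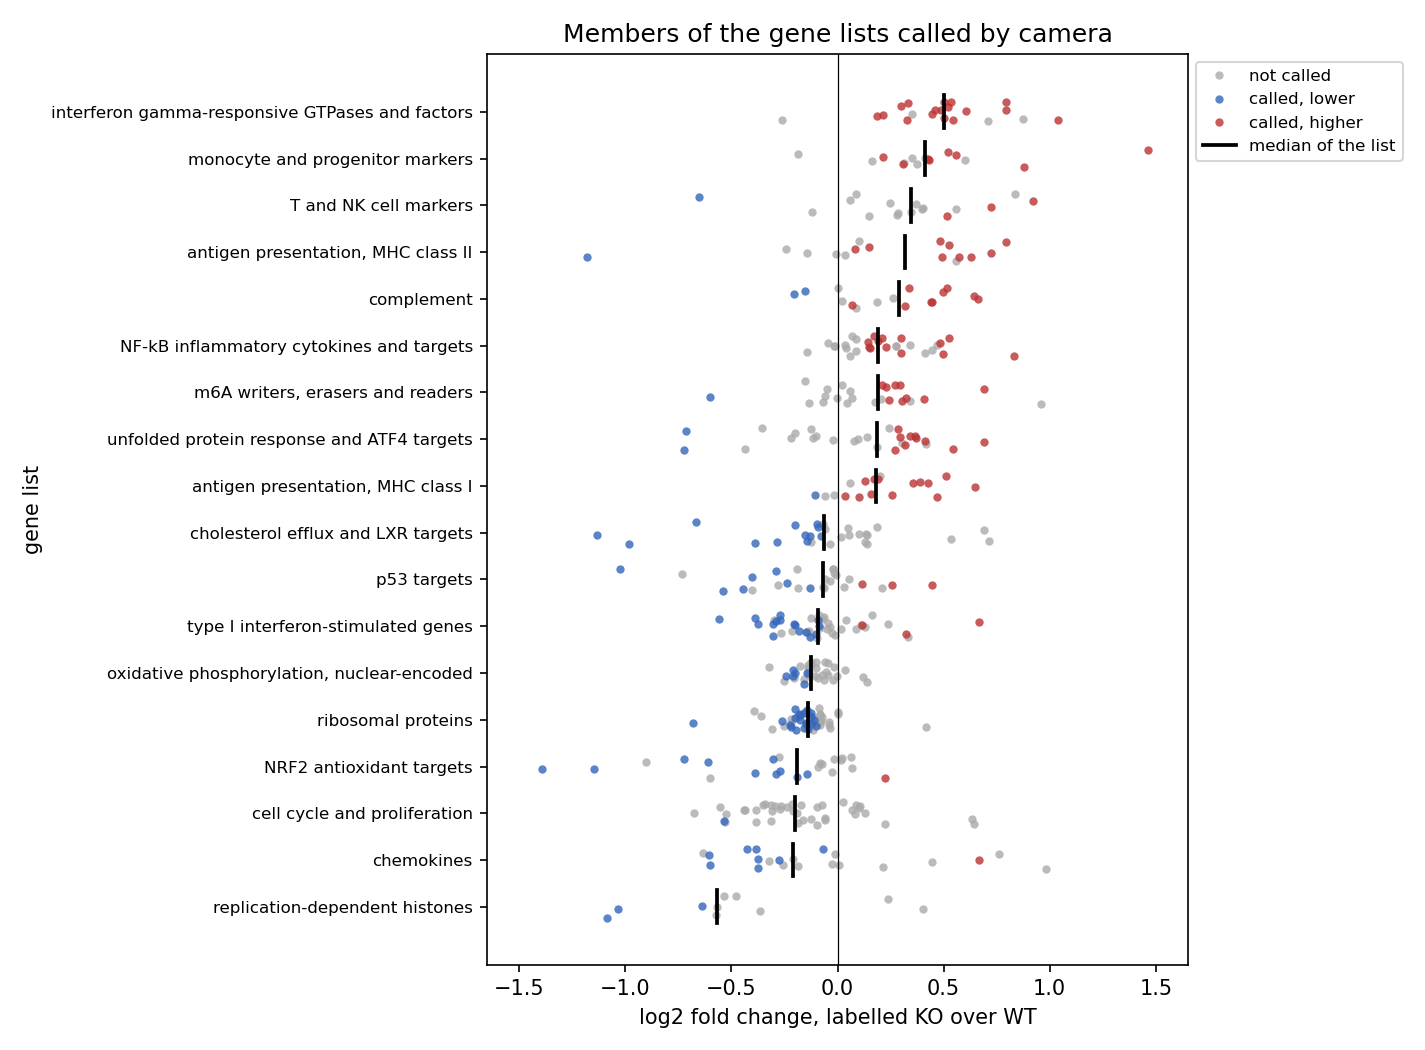
Log2 fold change (labelled KO over WT) of each tested member of the 18 gene lists called by camera, with 1 line per list and the list median as a black bar; red and blue points are genes called higher and lower, grey points were not called. The 9 lists called higher have medians of 0.18 to 0.50 and the 9 called lower have medians of -0.57 to -0.06; 2 members lie beyond the horizontal axis and are not drawn.

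The 22 macrophage identity genes went both ways in the libraries labelled KO, with 7 higher and 4 lower (9 and 7 adjusted over the list alone; camera adjusted p = 0.246). Fcgr1, with C1qa and Csf1r, rose (0.44) while Lyz2 fell. Of 30 phagocytic and scavenger receptor genes, 8 rose and 5 fell (10 and 6 adjusted over the list alone; camera adjusted p = 0.203). Fcgr4 rose from 437 to 625 FPKM and the bridging ligand gene Gas6 fell from 178 to 124 FPKM, with Cd36. Alternative activation markers numbered 22, of which 4 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.124). Stab1 and Il4ra rose by 0.33 and 0.43, and Mrc1 and Tgm2 fell by 0.46 and 0.14. Of 32 genes of Toll-like receptor signalling and its brakes, 7 rose and 1 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.0791). Tlr2, Socs3, Tlr13 and Tirap rose by 0.40, 0.42, 0.20 and 0.51. In the chemokine receptor list 5 of 14 rose and 2 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.160). Ccr1, Fpr2 and Fpr1 rose by 0.70, 0.61 and 0.47, and Cxcr4 fell by 0.28. Of 28 inflammasome and cell death genes, 8 rose and 3 fell (9 and 7 adjusted over the list alone; camera adjusted p = 0.399; 6 to 8 called with any 1 library left out). Mcl1 and Nlrc4, with Il1b, rose by 0.11 and 0.35, and Bcl2l1 fell by 0.36.

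Hypoxia, glycolysis, immediate early, lysosome, matrix and cholesterol biosynthesis lists were not called. For hypoxia, 4 of 20 genes rose and 1 fell in the libraries labelled KO (6 and 1 adjusted over the list alone; camera adjusted p = 0.0584; 2 to 4 called with any 1 library left out). Hif1a, Egln1 and P4ha1 rose by 0.21, 0.38 and 0.18 and Ndrg1 fell by 0.52. The call of P4ha1 was lost without WT replicate 1 or 2 or KO replicate 2 or 3 (edgeR adjusted p from 0.0521 to 0.0617), and that of Ndrg1 without any 1 library but KO replicate 2 (0.0704 to 0.0858). For glycolysis, 4 of 20 rose and 4 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.0971; 4 to 7 called with any 1 library left out). The lactate exporter gene Slc16a3, Hk2 and Pfkl rose by 0.40, 0.42 and 0.30, and Aldoa fell by 0.15. Of 29 immediate early and heat shock genes, 6 rose and 2 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.160; 4 to 7 called with any 1 library left out). Fosl2, Klf2 and Hsph1 rose by 0.57, 0.65 and 0.49, and Ier5 fell by 0.24. Of 35 lysosome and autophagy genes, 6 rose and 10 fell (7 and 10 adjusted over the list alone; camera adjusted p = 0.636; 10 to 12 called with any 1 library left out). Gpnmb, Ctsd and Sqstm1 fell by 0.21, 0.10 and 0.29 while Ctsc rose, and the list's median and mean (0.01 and 0.02) lay above 0 with the test leaning down. Of 23 matrix and osteoclast-linked genes, 4 rose and 5 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.511), among them Mmp14 (0.35), Mmp8 (0.53) and Spp1 (-0.44). For cholesterol biosynthesis, 1 of 25 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.711; 1 to 2 called with any 1 library left out). Insig1 fell by 0.25 and Lpin1 by 0.35. The call of Insig1 was lost without WT replicate 1 or 3 or KO replicate 1 or 2 (edgeR adjusted p from 0.0522 to 0.0619), and that of Lpin1 without any 1 library but KO replicate 1 (0.0549 to 0.117).

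Markers of other cell types were mostly not called as lists. Of 15 neutrophil markers, 3 rose and 2 fell in the libraries labelled KO (4 and 3 adjusted over the list alone; camera adjusted p = 0.657; 3 to 4 called with any 1 library left out). Csf3r and Mmp8 rose by 0.19 and 0.53 and Lcn2 fell by 0.28. Mpo rose by 1.46 from 0.197 FPKM, a call lost without WT replicate 1 or 3 or KO replicate 1 or 2 (edgeR adjusted p from 0.0602 to 0.0802). The neutrophil median was -0.12 and the mean 0.13, with the test leaning up. Of 12 dendritic cell markers, 2 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.362). H2-Eb1 rose, Bst2 fell, and Fscn1 rose by 0.44, a call lost without any 1 of the 6 libraries (edgeR adjusted p from 0.0699 to 0.135). Of 19 stromal and fibroblast markers, 1 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.399; 0 to 1 called with any 1 library left out). Dcn rose by 0.69 from 0.260 FPKM, and Vim and Acta2 fell by 0.18 and 0.42. The call of Dcn was lost without any 1 library but KO replicate 1 (edgeR adjusted p from 0.0923 to 0.109). Vim lost it without any 1 library but KO replicate 3 (edgeR adjusted p from 0.0566 to 0.0923), and Acta2 without any 1 but WT replicate 1 (0.0790 to 0.106). Of 8 endothelial and adipocyte markers, 2 rose and 1 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.474). Eng and Vwf rose by 0.36 and 0.53, and Pecam1 fell by 0.29, a call lost without any 1 library but KO replicate 1 (edgeR adjusted p from 0.105 to 0.139). None of 7 B and plasma cell markers was called by edgeR (0 and 0 adjusted over the list alone; camera adjusted p = 0.711), against 1 at an unadjusted p under 0.05, 0 by DESeq2 and 1 by limma. Igkc was at 3.08 FPKM in WT and 4.44 in labelled KO, and Ighm at 3.94 and 4.66. The erythroid and megakaryocyte list had 3 tested members, too few for camera, with Pf4 lower (-0.37) and 1 higher and 1 lower adjusted over the list alone. The mast cell, basophil and eosinophil list had 4 tested members, of which edgeR called 0, also 0 adjusted over the list alone, against 1 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma. Ccr3 was at 1.09 FPKM in WT and 0.743 in labelled KO and Kit at 0.635 and 0.801.

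Terms annotated in the deposited table were tested the same way. Of 3384 terms with 10 to 300 tested members, camera called 94, 62 higher and 32 lower in the libraries labelled KO, and 0 with an estimated correlation (231 at an unadjusted p under 0.05; fry, which does not compare a term with other genes, called 1273). The highest-ranked was a KEGG pathway of Staphylococcus aureus infection, which holds complement and MHC class II genes, with 23 of 41 genes higher and 1 lower (camera adjusted p = 5.82e-13, but adjusted p = 0.673 with an estimated correlation). Peptide antigen binding had 11 of 15 genes higher and 0 lower (camera adjusted p = 9.63e-07). The cytosolic large ribosomal subunit had 20 of 56 genes lower and 1 higher (camera adjusted p = 4.20e-08), and KEGG oxidative phosphorylation 17 of 118 lower and 0 higher (0.000180). The adjusted p with an estimated correlation was 0.673 for these terms too. Terms that camera did not call shared that value, so it does not tell single terms apart. With an estimated correlation, camera uses only the 4 residual degrees of freedom. That leaves little room for any of 3384 terms to pass, so the count of 0 cannot decide for or against them.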

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

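Counts divided by 4, limma with a pseudocount of 0.1, edgeR with the FPKM filter of 1, fry on terms, trend removal and the minimum log2 CPM were chosen after the data were seen. The count of called genes was 2060. It was 2684 with DESeq2, 1661 without a filter, and 1569 to 2261 over the other settings that kept all 6 libraries and no block. With 1 library left out it was 1244 to 1339, from fewer samples, and 114 genes passed a 2-fold minimum. The share of called genes that were higher, 55.3%, moved by under 10 percentage points with every scaling tried. Mettl3 was not called under any setting that tested it, and the filter at an FPKM of at least 5 left it out. Its log2 fold change, 0.02, turned to -0.0661 without WT replicate 3 and to -0.0552 without KO replicate 3. It was 0.03 to 0.11 without any other library.

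The values did not show that the replicate numbers pair the libraries, which does not exclude a pairing. Deviations of same-numbered libraries from their group means correlated at -0.02, -0.01 and 0.02, and replicate number 3 alone matched its own number best. With a replicate block, edgeR called 1012 genes (552 higher, 460 lower) and limma also 1012 (590 higher, 422 lower), and edgeR kept the calls of 125 of 152 named genes. The block leaves fewer residual degrees of freedom.

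Camera called 18 lists, 9 with an estimated correlation and 29 by fry, which tests another question, and 14 to 21 over the other settings. None of the 18 lost its call with 1 library left out. Of 94 terms, 0 stayed with an estimated correlation, fry called 1273, and 80 to 100 were called with the block or 1 library left out. Some lists that lost their call had an estimated correlation below the preset 0.01. These were chemokines (-0.033), T and NK cell markers (-0.027), unfolded protein response and ATF4 targets (-0.019), p53 targets (-0.016) and replication-dependent histones (-0.0064). There the values argue against a higher correlation as the cause. With an estimated correlation, camera takes p from 4 residual degrees of freedom, far fewer than with the preset, which raises p-values by itself. The interferon gamma list, at an estimate of 0.0135, kept its call, yet its unadjusted camera p went from 4.72e-21 to 0.000788. The other lists that lost their call had estimates above 0.01. For them and for the terms, correlation and degrees of freedom were not told apart. Lists and terms were not run with DESeq2.

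Over 14 settings, the 152 named called genes kept their call in 2010 of 2056 comparisons, lost it in 46 and reversed in 0, and the 18 named genes that were not called gained a call in 6 of 224. With 1 library left out, 126 of the 152 kept the call in all 6 fits. Depth was not varied here.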

Other observations

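The tests on Mettl3, on Lyz2, on pseudogene reads and on the length and GC trend were chosen only after the results they bear on were seen, the m6A-site regression without exon number and the comparison of genes with no site were run after the regression with exon number was seen, and the genes and terms of the next paragraph were picked after their values were seen.

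Of the granzyme genes not already named, those that rose in the libraries labelled KO were Gzmc, from 15.2 ± 0.684 to 26.1 ± 0.638 FPKM (SD, n = 3; log2 fold change 0.76) and Gzme, from 5.41 ± 0.805 to 9.69 ± 0.497 FPKM (0.82), while Gzmf (0.32, SE 0.26), Gzmk (0.58, SE 0.64) and Gzmm (0.24, SE 0.49) were not called. Gzmb, Gzmc, Gzmd, Gzme, Gzmf and Gzmg lie together on chromosome 14 from 56117626 to 56262260, between 3.82 and 3.96 Mb from Mettl3, and close paralogs can share reads. Among the other genes within 10 Mb of Mettl3, 22 of 210 were called (10.5%), against 12.7% elsewhere. Among annotation terms, rotational proton-transporting ATPase activity had 7 of 16 genes lower and 0 higher (camera adjusted p = 0.000740) and eosinophil chemotaxis 7 of 11 lower and 0 higher (0.000138). The endoplasmic reticulum lumen had 28 of 80 genes higher and 4 lower (camera adjusted p = 0.000183), and histone-lysine methyltransferase activity 8 of 25 higher and 0 lower (0.00447). With an estimated correlation the adjusted p was 0.673 for each of these terms, a value that uncalled terms shared.

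Mettl3 was not lower in the libraries labelled KO. An exchange of libraries between the groups is argued against, since the lowest WT Lyz2 value was 2.31 times the highest in labelled KO; a wrong label shared by a whole group was not tested. Tox4 shares 18.4% of the exonic length of Mettl3 and was at 17.7 ± 0.0832 FPKM in WT and 18.8 ± 0.511 in labelled KO. Its reads could make up an unknown share of the Mettl3 value, and values per gene leave this open. A deletion that leaves most of the transcript also stays open. The 95% limits of the log2 fold change, -0.29 and 0.34, allow a gene total down to a ratio of 0.816 but set no bound on single exons. Exon-level reads were not analysed here, and the genotype itself was not tested.

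Lyz2 was lower in the libraries labelled KO. Loss of 1 of 2 copies with no other change would give a ratio of 0.5, which lies outside the 95% limits of 0.408 and 0.430. Those limits measure only the spread between these libraries, which may be technical, so they do not exclude copy loss alone. Copy loss together with another change stays open too. Reads moving to Lyz1 are argued against, since its rise was 0.108% of the CPM that Lyz2 lost. A lower share of macrophages is argued against by the other 21 macrophage identity genes, with a median log2 fold change of 0.0681 (SD 0.24, range -0.33 to 0.49) against -1.26. A candidate explanation is a difference at the Lyz2 locus or in its regulation between the genotypes, which these data do not test further.

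Ribosomal protein and oxidative phosphorylation genes were called lower as lists in the libraries labelled KO, with 21 of 50 and 6 of 34 members called lower, though the ribosomal call was lost with an estimated correlation (camera adjusted p = 0.0528). A trend with length and GC content is argued against as the whole cause: with it removed, the larger camera adjusted p of the lists was 0.00444, while the medians shrank from -0.14 to -0.10 and from -0.13 to -0.09, so part of the size may follow it. For oxidative phosphorylation, pseudogene reads are argued against by a median of -0.124 in the 29 members without a named pseudogene, and 12 of the 15 with no 31-base stretch in an annotated pseudogene were below 0; for ribosomal proteins they cannot be told apart, because every transcript shares at least 2.49% of such stretches, the 11 members without a named pseudogene (median -0.12) included, and 0 of 50 members had an upper 95% limit below the loss of all shared sequence. Fewer m6A-prone sites, counted as GGACT over 200 nt from exon junctions, are argued against as the whole cause only for sites so counted. Among genes with no such site, the log2 difference of the lists from the other genes changed by -0.125 (SE 0.0206, 38 ribosomal members) and -0.0965 (SE 0.0138, 28 oxidative phosphorylation members). Those genes were not matched for length or GC content, and m6A sites of other sequence or position were not counted. The comparison therefore cannot decide about m6A sites in general. As a part of the cause, the counted sites cannot be told apart. Their slope per site was 0.00639 (SE 0.00143) at equal length, GC content and abundance, against -0.00292 (SE 0.00156) for sites within 100 nt. With exon number added the slopes were -0.000159 (SE 0.00150) and 0.00586 (SE 0.00169), over 8530 genes that are not independent. A biological effect of the labelled genotype stays open.

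The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. For each of genes, lists and terms, 1 of the 10 splits, the real one, gave a count as large: 2060 genes against at most 8 in another split, 18 lists against at most 6, and 94 terms against at most 1. Each other split, with WT and labelled KO libraries mixed, still called 1 to 6 lists.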
